A study of Mus musculus with 20 samples.

How the data were processed

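Cultures of the mouse line ATDC5 were sampled on days 0, 4, 7, 14 and 21. Per the labels' protocols, RNA was extracted with a kit for fibrous tissue, mRNA was selected by its poly-A tail, and cDNA was made from fragmented mRNA with random hexamers. The medium changed after day 0 from growth to differentiation medium, per the labels' protocols. The labels do not say whether the replicates of a day were separate cultures, so p-values measure the spread between these samples, which may be technical.

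The deposited values are raw read counts per gene, 1 library per file. Per the submitters' processing notes, the tools were FastQC 0.74, Trim Galore 0.6.7, STAR 2.7.11a and featureCounts 2.0.6 with genome build mm39. The notes as used here give no order, settings, annotation or strand mode. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart, and members of families with near-identical copies are uncertain (Oas, Mx, Gbp, Ifit, Ifi44, Prl2c, Eif1ad and osteocalcin genes, and mitochondrial genes with nuclear copies). Each file lists 56951 features, of which 535 carry an Ensembl identifier in place of a symbol. Gene names are those of the files. The annotation at hand is of another build, so no coordinates are given and only gene lengths and GC content were taken from it.

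Groups were the 5 sampling days, with 4 libraries each except day 4 with 3. Replicate 3 of day 4 has no file, and its label says that it failed in processing. Total counts per library were 21523358 to 47539462, 20986 to 25099 genes had at least 1 count, and 99.92% to 99.95% of counts lay in the genes tested. Ribosomal RNA of Rn18s-rs5 took 0.679% to 1.84% of counts. A fold change against a day without any count is given as a lower bound, computed against 3 counts over the libraries of that day. Folds are not given for genes with 1 to 3 counts on a day, only levels. Such bounds and floors cover counting error only, since PCR copies are not independent molecules.

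All 19 libraries entered a single model with 1 term per day in edgeR 4.0.16 under R 4.3.3, after filterByExpr (16483 genes kept) and TMM scaling (factors 0.951 to 1.067). This left 14 residual degrees of freedom, and the common biological coefficient of variation was 5.05%. Genes were tested with edgeR's quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p under 0.05. Genes changed at least 2-fold (an absolute log2 change of 1 or more) were also counted. There were 7 comparisons, of consecutive days and of each later day against day 0, and a test of all 4 day terms together. Levels in CPM are on the counts-per-million scale, with TMM-scaled library totals. Principal components used log2 CPM with a prior count of 2.

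The 32 gene lists (586 distinct genes) were tested in the 5 main comparisons with camera from limma 3.58.1, with a preset correlation between genes of 0.01, adjusted over all 160 tests. The same tests were run with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. For each list the members that rose or fell are counted as adjusted over all genes, and the count adjusted over the list alone is given where it differs. The lists are cartilage matrix, chondrogenic regulators, hypertrophic chondrocyte, osteoblast and mineralisation, fibroblast and tendon, all collagen chains, small leucine-rich and other proteoglycans, basement membrane, collagen processing, glycosaminoglycan synthesis, matrix proteases and inhibitors, cell cycle, cell cycle exit, BMP and TGF-beta, Wnt, hedgehog response, insulin-like growth factor axis, sterol synthesis, selenoproteins, iron handling, glycolysis and hypoxia, unfolded protein and amino acid stress, immediate early, interferon response, mitochondrially encoded mRNAs, adipocyte, skeletal muscle, smooth muscle and myofibroblast, endothelial, leukocyte and osteoclast, neural and glial, and epithelial and pluripotent. Some genes stand in several lists, for example 10 of the 22 cartilage matrix genes listed.

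Genes were named by a fixed rule. It takes 16 key genes whatever their values. For each of the 5 main comparisons it adds the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 2, no overlap between the libraries of both days, and an established symbol. It also takes up to 4 called members of each list by size of change, and the 4 genes with the smallest F-test p among those highest on each day. The days' libraries do not overlap for any gene named as a largest rise or fall. The tests, the lists, the naming rule and the alternatives, other than those added later, were fixed before the data were examined.

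The 7 comparisons and the test over time were run on simulated counts with known changes, drawn from the overall means, totals and dispersions of these libraries. In each run 67, 67 and 66 genes above a minimum count were changed 1.5-, 2- and 4-fold, as many up as down. All other genes were equal on every day. The real libraries differ in far more genes, not always evenly up and down, so these rates need not hold for them. For day 4 against day 0, edgeR recovered 67.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 false calls among 170. For day 7 against day 4 these were 61.2%, 83.6% and 90.9%, with 3 false calls among 160. For day 14 against day 7 they were 68.7%, 74.6% and 98.5% (6 false calls among 167). For day 21 against day 14 they were 64.2%, 83.6% and 97.0% (8 among 171), and for day 21 against day 0 they were 67.2%, 91.0% and 95.5% (11 among 180). For day 7 against day 0 they were 65.7%, 73.1% and 95.5% (5 false calls among 161), and for day 14 against day 0 they were 74.6%, 85.1% and 97.0% (6 among 177). The test over time, with genes changed on day 4 only, recovered 70.1%, 77.6% and 100%, with 15 false calls among its 180.

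The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, scaling to total counts only, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, fits of only the libraries of the 2 days compared, a block for the replicate number, and leaving out each library in turn. A fit without ribosomal RNA and mitochondrial genes, and the lists without a low-count filter, were added after seeing the data. The 40 list calls that camera made only with the preset correlation are marked as such wherever they are printed.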

Results

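RNA was sequenced from cultures of ATDC5, a mouse embryonal carcinoma line that behaves as a cartilage progenitor, on days 0, 4, 7, 14 and 21 of a differentiation culture. Each day has 4 libraries except day 4, which has 3 because replicate 3 of that day has no file. The files of the 19 libraries hold read counts for 56951 genes, and 16483 of these were abundant enough to test. Total counts per library ran from 21523358 to 47539462, with a median of 26385801. A gene with 3 counts in a library therefore lies between 0.0631 and 0.134 on the counts-per-million scale (CPM). Day 0 cells were in growth medium, and all later days were in a differentiation medium with insulin, transferrin, selenite and ascorbic acid and with less serum. Comparisons with day 0 thus mix time and medium. Levels are means ± SD in CPM over the libraries of a day (n = 3 on day 4, n = 4 on every other day), and changes are log2 fold changes ± SE. The SE is the absolute change divided by the square root of the F statistic. For large changes from a few counts it is smaller than the counting error and is too tight. Examples are Mx1 on day 4 and Adm and Gbp8 on day 21 (8, 5 and 4 counts on day 0). F13a1, Comp and Col10a1 on day 21 against day 0 are further examples (44, 22 and 19 counts on day 0). SEs of other genes with few counts on a day may be too tight as well.

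Libraries of the same day lay close together. The Spearman correlation across genes was 0.994 to 0.995 between libraries of one day and 0.931 to 0.988 between libraries of different days. The first principal component held 48.4% of the variance and separated day 0 from all later days. The second held 27.8% and ordered the later days from day 4 to day 21.

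**Figure D1:**
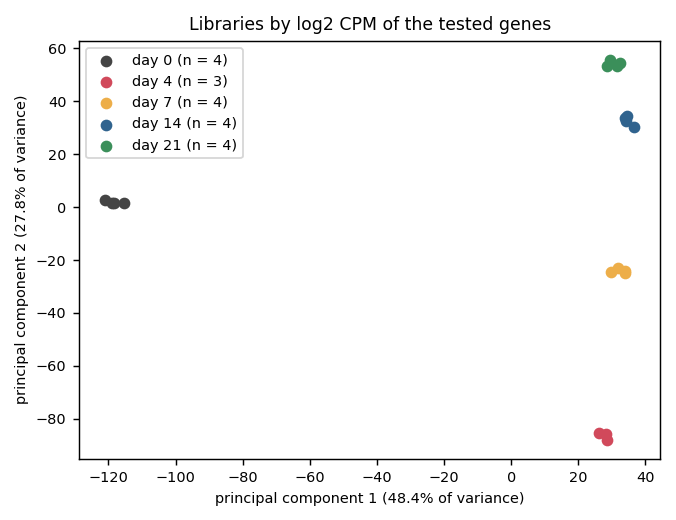
Each point is 1 of the 19 libraries, coloured by day, on the first (48.4% of the variance) and second (27.8%) principal components of log2 CPM. Day 0 lies apart on the x axis, and days 4, 7, 14 and 21 follow one another on the y axis.

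Between consecutive sampling days, 7766 to 11382 genes changed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). From day 0 to day 4, 5993 genes rose and 5389 fell, and 2880 rose and 1235 fell at least 2-fold (2169 and 743 with a filter of at least 1 CPM in at least 3 libraries). From day 4 to day 7, 4385 rose and 4279 fell, 752 and 779 of them at least 2-fold. With total counts only, 4942 rose and 3814 fell in this step, while under several other alternatives, given further below, falls outnumbered rises. From day 7 to day 14, 3909 rose and 3884 fell, 401 and 755 at least 2-fold. Scaled to total counts only, 2917 rose and 5139 fell in this step, 338 and 870 of them at least 2-fold. From day 14 to day 21, 3423 rose and 4343 fell, 423 and 499 at least 2-fold (243 and 347 with the same filter). With total counts only, 5872 rose and 2595 fell between days 14 and 21, 618 and 376 of them at least 2-fold, and the median log2 change of all genes moved from -0.02 to 0.12. Changes below are relative to the median gene. Between day 0 and day 21, 6502 genes rose and 6028 fell, 3124 and 1631 at least 2-fold. Day 7 against day 0 gave 6222 rises and 5499 falls, and day 14 against day 0 gave 6286 and 5609. With total counts only, falls outnumbered rises for day 4 against day 0 (5608 rises, 5889 falls) and day 14 against day 0 (5684 rises, 6370 falls).

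**Figure D2:**
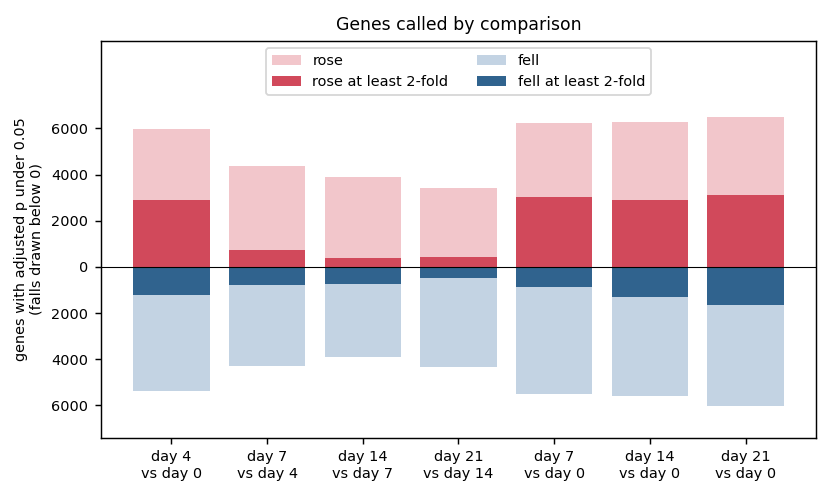
Bars give the number of genes that rose (above 0) or fell (below 0) in each of the 7 comparisons, with genes changed at least 2-fold in the darker shade. The day 4 against day 0 bars reach 5993 rises and 5389 falls.

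The step from day 0 to day 4 asks what differs after the start of differentiation. Genes of the antiviral interferon response were among the largest rises. Mx1, an antiviral GTPase, went from 0.0610 to 727 ± 37.9 CPM, a log2 change of 13.27 ± 0.14. Oas3 and Oas2, which make the messenger that activates RNase L, reached 752 ± 15.9 and 206 ± 3.34 CPM from 0.108 and 0.0285. Ifi44l (124 ± 4.70 CPM, at least 4744-fold) and Oas1g (107 ± 4.03 CPM, at least 4090.1-fold) had no counts in any day 0 library. All 22 measured members of the interferon response list rose, with a median log2 change of 7.13 (adjusted p = 9.8e-131). With an estimated correlation the adjusted p of this list was 0.00019. The other list calls that hold with an estimated correlation are printed with the p of the preset correlation only. Rsad2, which encodes the antiviral enzyme viperin, rose by 10.00 ± 0.16 to 1185 ± 128 CPM, and Isg15, a ubiquitin-like modifier, rose by 9.31 to 294 CPM. Mx, Oas, Ifit and Ifi44 genes belong to families of similar sequence, so how reads divide between members is uncertain. Outside the lists, Apod, a lipid-binding apolipoprotein, went from 0 to 370.4 ± 33.2 CPM (at least 14210-fold).

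Extracellular matrix genes rose as well. Col2a1, the main cartilage collagen, rose from 25.2 ± 1.06 to 187 ± 29.4 CPM (2.90 ± 0.08, adjusted p = 2.9e-28), and Acan, the core protein of the cartilage proteoglycan aggrecan, from 1.41 ± 0.218 to 20.04 ± 3.75 CPM (3.86 ± 0.14). Of 20 measured cartilage matrix genes 15 rose and 1 fell. Their median log2 change was 2.62, or 2.48 with Snorc, which has no counts on day 0, at its bound (adjusted p = 8.9e-05; adjusted p = 0.149 with an estimated correlation). Hapln1, which links aggrecan to hyaluronan, went from 0.111 ± 0.0877 to 8.18 ± 2.92 CPM. The 39 measured collagen chains gave 34 rises and 2 falls (35 rises adjusted over the list alone; median 1.66, or 1.65 with 1 chain at its bound; adjusted p = 1.6e-08). Among small leucine-rich and other proteoglycans 12 of 15 rose and 3 fell (median 1.95, adjusted p = 5.8e-13), led by Aspn, which went from 7.54 to 314 CPM. In the fibroblast and tendon list 18 of 20 rose and 1 fell (median 1.00, adjusted p = 3.7e-10), among them the collagen-binding proteoglycans Lum (5.24 ± 0.14) and Dcn (4.28 ± 0.09). Basement membrane genes also rose, 14 of 19 with 3 falls (median 1.39, adjusted p = 9.3e-06), including the laminin chain Lama4, which went from 18.8 to 124 CPM.

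Genes of dividing cells fell. Of 30 cell cycle genes 23 fell and 3 rose (median -1.29, adjusted p = 5.2e-18). Mki67, a marker of cycling cells, went from 511 to 154 CPM (-1.73 ± 0.05), and Bub1b, a spindle checkpoint kinase, from 233 to 57.8 CPM. The cyclin-dependent kinase inhibitor Cdkn1a rose from 1.35 to 42.0 CPM (5.04 ± 0.12). The largest single falls were in Selp, the adhesion receptor P-selectin (-4.54 ± 0.11, 68.6 to 3.10 CPM), and Prl2c2, a prolactin-family gene with near-identical copies (-3.86 ± 0.14). G0s2, an inhibitor of triglyceride breakdown, changed by -2.99 ± 0.14. Itga11, a collagen-binding integrin, changed by -2.69 ± 0.08, and Lgr4, an R-spondin receptor, by -2.61 ± 0.06. Plxna4, a semaphorin receptor, changed by -2.53 ± 0.12.

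The immediate early, stress and Wnt lists rose in the same step. All 16 immediate early genes rose (median 1.76, adjusted p = 3.2e-10), for example Atf3 from 3.52 to 102 CPM. In the unfolded protein and amino acid stress list 13 of 18 rose and 2 fell (median 0.76, adjusted p = 5.0e-08), with Ddit3 going from 11.6 to 109.9 CPM. Of 22 Wnt genes 16 rose and 1 fell (median 1.22, adjusted p = 0.0026), led by the secreted antagonist Frzb (4.60). All 22 glycolysis and hypoxia genes rose (median 0.65, adjusted p = 8.3e-06; adjusted p = 0.243 with an estimated correlation), Vegfa from 39.0 to 186 CPM. Hypertrophic chondrocyte genes gave 15 rises and 2 falls of 18 (median 1.82, adjusted p = 1.0e-05; adjusted p = 0.0704 with an estimated correlation), with the bone sialoprotein gene Ibsp going from 1.97 to 137 CPM. Osteoblast and mineralisation genes gave 11 rises and 2 falls of 16 (median 1.49, adjusted p = 0.0036; adjusted p = 0.0778 with an estimated correlation). In the insulin-like growth factor list 8 of 13 rose and 4 fell (median 0.31, adjusted p = 0.0241; adjusted p = 0.0905 with an estimated correlation, and 0.0127 to 0.0905 over the alternatives). There the binding protein gene Igfbp4 rose by 5.62 ± 0.07 and Igfbp3 changed by -1.49. All 8 measured mitochondrially encoded mRNAs fell (median -1.73, adjusted p = 8.3e-06; adjusted p = 0.115 with an estimated correlation), and their share of all counts went from 0.992% ± 0.0152 to 0.335% ± 0.0481. The share of mitochondrial ribosomal RNA went from 0.0340% ± 0.000281 to 0.0615% ± 0.00862, with mt-Rnr1 rising by 2.27 ± 0.12 and mt-Rnr2 at 251 and 213 CPM (adjusted p = 0.140). Collagen processing genes gave 18 rises and 5 falls of 28 (median 0.43, adjusted p = 0.0253; adjusted p = 0.481 with an estimated correlation). Matrix proteases and inhibitors gave 12 rises and 6 falls of 20 (median 0.61, adjusted p = 0.0227; adjusted p = 0.134 with an estimated correlation).

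Sox9, the master transcription factor of cartilage, rose by 0.15 ± 0.05 to 129.7 ± 2.38 CPM (adjusted p = 0.0066; 0.0018 to 0.0566 over the alternatives, the highest with total counts only). The level of Runx2, a driver of hypertrophy and bone formation, was 238 CPM on day 0 and 247 on day 4, a difference within the error (adjusted p = 0.308). Col10a1, the collagen of hypertrophic cartilage, was at 0.161 ± 0.0352 and 0.459 ± 0.345 CPM, and its rise (adjusted p = 0.00098; 5.1e-05 to 0.313 over the alternatives) rested on day 4 replicate 4, without which the change was 0.68 (adjusted p = 0.313). Limma-voom did not call it either (adjusted p = 0.0608). Day 4 replicate 4 was also the highest library of its day for Col2a1, Acan, Col9a1, Comp and Matn3. Its Col2a1 level was 218 CPM, against 160 and 184 CPM in replicates 1 and 2. For Sox9 (128 CPM against 132 and 129) and Ihh it was not the highest. Col1a1 and Col3a1, the fibrillar collagens of skin, tendon and bone, rose by 1.05 ± 0.04 and 1.92 ± 0.05. Col1a2 rose by 0.21 ± 0.04, Alpl, the phosphatase of mineralising cells, by 0.32 ± 0.05, Comp by 2.75 ± 0.34, Col9a1 by 5.12 ± 0.30 and Mmp13, a collagenase, by 2.25 ± 0.28. Matn3, a cartilage matrix linker, went from 0.0769 to 0.379 CPM (adjusted p = 0.0017; 1.4e-05 to 0.107 over the alternatives, the highest without day 4 replicate 4). Ihh, a growth plate signal, had 1 count on day 0 and 8 on day 4 (adjusted p = 0.0389), and this call was lost with limma-voom, without a low-count filter, and without day 0 replicates 1, 3 or 4 or day 4 replicates 2 or 4 (adjusted p 0.0504 to 0.153 in those fits, 0.0151 to 0.153 over all alternatives).

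**Figure D3:**
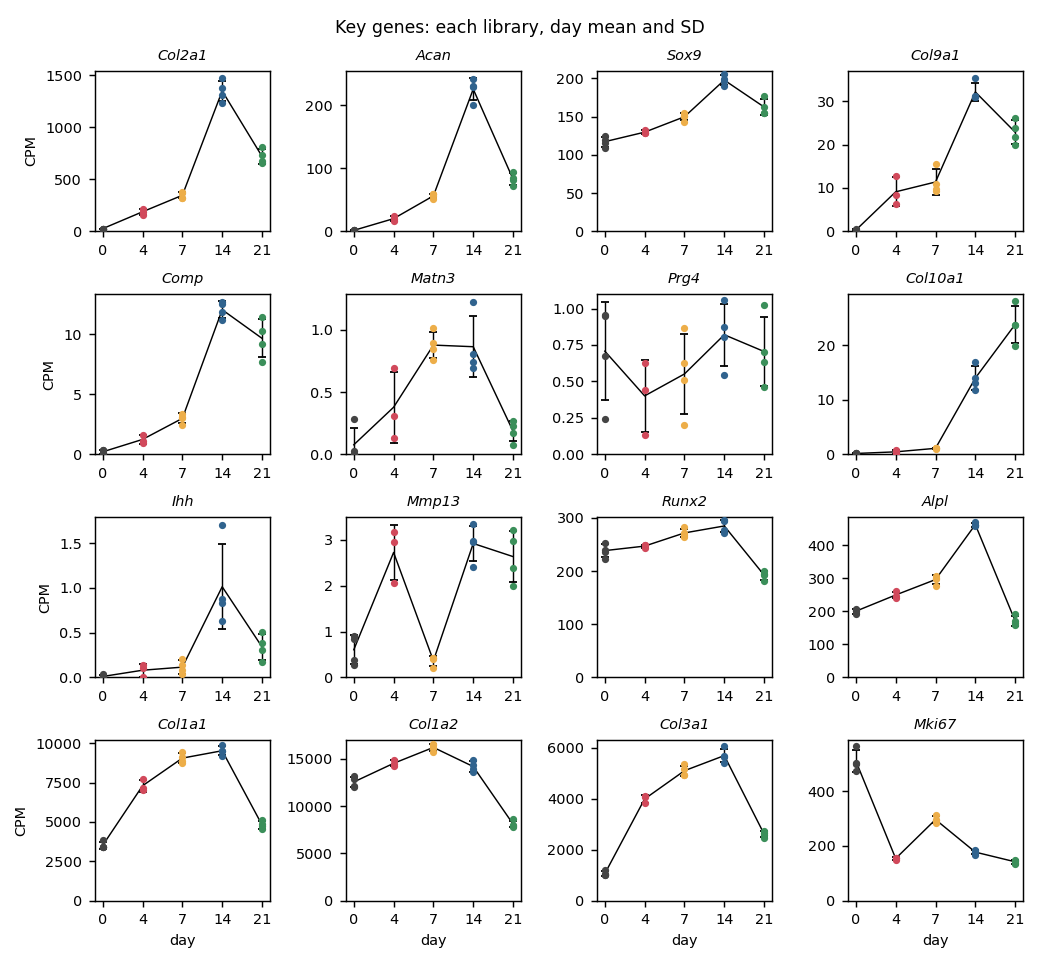
Each panel plots 1 of the 16 key genes in CPM (y axis) against the sampling day (x axis, days equally spaced), with a point per library and the day mean ± SD. Col2a1 and Acan are highest on day 14, at 1349.8 and 226 CPM, and Col10a1 on day 21, at 23.8 CPM.

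Between day 4 and day 7 the interferon genes came down again. Of the 22 in the list 21 fell and 1 rose (median -1.84, adjusted p = 2.3e-74). Mx1 went from 727 to 60.6 ± 1.77 CPM (-3.59 ± 0.06), and the DNA and RNA sensor Zbp1 from 383 to 33.1 ± 1.08 CPM (-3.53 ± 0.06). The chemokines Cxcl10 (-3.19 ± 0.08) and Cxcl11 (-3.07 ± 0.09) and the antiviral enzymes Rsad2 (-3.07 ± 0.10) and Cmpk2 (-2.97 ± 0.07) completed the 6 largest falls. The stress list fell as well, 12 of 18 with 3 rises (13 falls adjusted over the list alone; median -0.33, adjusted p = 0.00014), for example the asparagine synthetase gene Asns from 305 to 157 CPM. Immediate early genes gave 9 falls and 3 rises of 16 (median -0.63, adjusted p = 0.0080; adjusted p = 0.186 with an estimated correlation).

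All 22 glycolysis and hypoxia genes rose from day 4 to day 7 (median 0.71, adjusted p = 2.7e-20). The largest rises of this step included Egln3, a prolyl hydroxylase of the oxygen-sensing pathway (2.39 ± 0.09, 9.44 to 49.3 CPM), and Car9, a carbonic anhydrase induced by low oxygen (2.22 ± 0.12, 6.81 to 30.4 CPM). Susd5 (2.33 ± 0.10), Frzb (2.29 ± 0.10), the selenium-binding protein gene Selenbp1 (2.13 ± 0.10) and Plxdc1 (2.04 ± 0.12) were the others. Cell cycle genes rose, 21 of 30 with 4 falls (median 0.64, adjusted p = 4.7e-14), and Mki67 went from 154 to 297 CPM (0.94 ± 0.05). In the insulin-like growth factor list 10 of 13 rose and 1 fell (median 0.50, adjusted p = 2.3e-05), with Igf1 going from 19.9 to 79.1 CPM.

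Matrix genes rose further by day 7. Col2a1 reached 346 ± 30.3 CPM (0.88 ± 0.07) and Acan 56.2 ± 3.59 CPM (1.45 ± 0.09), and Comp, an oligomeric cartilage protein, rose by 1.18 ± 0.21. Of 20 cartilage matrix genes 10 rose and none fell (median 0.97, adjusted p = 6.8e-05; adjusted p = 0.0731 with an estimated correlation). Collagen chains gave 27 rises and 2 falls of 39 (28 and 3 adjusted over the list alone; median 0.41, adjusted p = 2.2e-06), and the proteoglycan list 9 rises and 2 falls of 15 (median 0.86, adjusted p = 1.8e-08). Basement membrane genes gave 15 rises and 3 falls of 19 (median 0.62, adjusted p = 1.2e-05), and hypertrophic chondrocyte genes 13 rises and 2 falls of 18 (median 0.33, adjusted p = 3.5e-05). The phosphoprotein gene Spp1 went from 308 to 899 CPM, whereas Mmp13 went from 2.72 to 0.364 CPM (-2.90 ± 0.30). Other calls lost with an estimated correlation were those for smooth muscle and myofibroblast (7 rises of 11, 8 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation), collagen processing (18 rises, 2 falls of 28; adjusted p = 0.211 with an estimated correlation), fibroblast and tendon (16 rises, 3 falls of 20, 17 rises adjusted over the list alone; adjusted p = 0.0905 with an estimated correlation) and osteoblast and mineralisation (14 rises, 1 fall of 16; adjusted p = 0.0766 with an estimated correlation). Among chondrogenic regulators 8 of 17 rose and 3 fell (10 rises adjusted over the list alone; adjusted p = 0.0364; adjusted p = 0.108 with an estimated correlation, and 0.0077 to 0.108 over the alternatives), and Sox9 rose by 0.21 ± 0.05. Glycosaminoglycan synthesis gave 14 rises and 3 falls of 27 (15 rises adjusted over the list alone; adjusted p = 0.0418; adjusted p = 0.126 with an estimated correlation). That call was also lost with the stricter count filter (adjusted p = 0.0607) and without day 7 replicate 4 (0.0543), and ranged from 0.00045 to 0.126 over the alternatives. Col9a1 (0.25 ± 0.16, adjusted p = 0.184) and Matn3 (1.06 ± 0.49, adjusted p = 0.0683) were not called by edgeR in this step. Without day 4 replicate 4 both were, with changes of 0.63 and 1.96 (adjusted p = 0.0021 and 0.0130, the lowest over the alternatives, where the highest were 0.842 and 0.283). Matn3 was also called by DESeq2 (adjusted p = 0.0448), by limma-voom (0.0243) and in a fit of both days alone (0.0294), and Col9a1 without a count filter (0.0327).

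From day 7 to day 14 cartilage matrix genes rose again. Col2a1 went from 346 ± 30.3 to 1349.8 ± 99.7 CPM (1.96 ± 0.07), Acan from 56.2 ± 3.59 to 226 ± 17.3 CPM (2.01 ± 0.07) and Hapln1 from 23.9 to 144 ± 8.16 CPM (2.59 ± 0.09). Of 20 cartilage matrix genes 10 rose and 2 fell (median 0.97, adjusted p = 7.8e-14), and of 17 chondrogenic regulators 10 rose and 2 fell (median 0.34, adjusted p = 5.8e-05). The receptor gene Fgfr3, which restrains chondrocyte growth, went from 19.8 to 68.7 CPM (1.79 ± 0.06), and the Sox9 partner Sox6 from 29.4 to 59.5 CPM. Sox9 rose by 0.40 ± 0.04 to 198 ± 6.16 CPM. In the proteoglycan list 11 of 15 rose and none fell (median 0.64, adjusted p = 7.6e-18), for example the fibril-binding Fmod from 66.6 to 306 CPM. Of 27 glycosaminoglycan synthesis genes 19 rose and 1 fell (median 0.26, adjusted p = 7.5e-06), including Xylt1, which starts the sugar chains of proteoglycans (37.4 to 90.4 CPM). Collagen processing genes gave 22 rises and 3 falls of 28 (median 0.40, adjusted p = 4.1e-09; adjusted p = 0.0731 with an estimated correlation). Other matrix lists were mixed. Collagen chains gave 17 rises and 11 falls of 39 (median 0.10, adjusted p = 0.0013; adjusted p = 0.149 with an estimated correlation), and the fibroblast and tendon list 9 rises and 4 falls of 20 (median 0.09, adjusted p = 0.0064; adjusted p = 0.290 with an estimated correlation). Basement membrane genes gave 5 rises and 6 falls of 19 (adjusted p = 0.170).

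Genes of hypertrophic and mineralising cells rose in the same week. Of 18 hypertrophic chondrocyte genes 15 rose and none fell (median 0.96, adjusted p = 1.9e-16). Col10a1 went from 1.10 ± 0.0992 to 14.0 ± 2.16 CPM (3.66 ± 0.16), Ihh from 0.115 to 1.01 CPM (3.14 ± 0.53), Mmp13 from 0.364 to 2.92 CPM (2.99 ± 0.29), and the channel gene Panx3 from 47.2 to 151 CPM. Alpl rose by 0.64 ± 0.04 to 463 ± 5.78 CPM. In the osteoblast and mineralisation list 10 of 16 rose and 1 fell (median 0.39, adjusted p = 0.00010), led by the osteocalcin genes Bglap and Bglap2 (2.75 and 2.61), a pair of near-identical copies. Runx2 was at 285 CPM on day 14 and 272 on day 7 (adjusted p = 0.159), and Col1a1 at 9526 and 9057 CPM (adjusted p = 0.130). Col1a2 changed by -0.19 ± 0.03. Col3a1 rose by 0.16 ± 0.04 (adjusted p = 0.0027), a call lost with total counts only (adjusted p = 0.0770, range over the alternatives 3.1e-06 to 0.0770).

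Other large rises were in Frzb (2.58 ± 0.07, 15.98 to 95.5 CPM), the angiotensin precursor Agt (2.56 ± 0.10), the cross-linking enzyme subunit F13a1 (2.42 ± 0.05, 37.7 to 202 CPM), the small heat shock protein gene Hspb7 (2.33 ± 0.09) and Prss35 (2.32 ± 0.04, 42.9 to 214 CPM). Wnt genes gave 12 rises and 6 falls of 22 (14 rises adjusted over the list alone; median 0.54, adjusted p = 0.0020), insulin-like growth factor genes 8 rises and 1 fall of 13 (9 rises adjusted over the list alone; median 0.24, adjusted p = 7.1e-05). Of 22 glycolysis and hypoxia genes 21 rose and 1 fell (median 0.51, adjusted p = 4.7e-14; adjusted p = 0.0692 with an estimated correlation). In the smooth muscle and myofibroblast list 7 of 11 rose (median 0.47, adjusted p = 0.00013), with the actin gene Acta2 going from 472 to 831 CPM. In the adipocyte list 6 of 7 genes rose (median 0.85, adjusted p = 0.00042), among them the fatty acid binding protein gene Fabp4 from 0.417 to 3.70 CPM. The interferon list fell again, all 22 members (median -1.85, adjusted p = 4.5e-112), with Zbp1 (-3.87 ± 0.10), Oas2 (-3.69 ± 0.07), Oasl1 (-3.51 ± 0.12), the master regulator Irf7 (-3.33 ± 0.09, 125 to 12.3 CPM), Mx1 (-3.28 ± 0.08) and Mx2 (-3.12 ± 0.10) as the largest falls of the step. Of 30 cell cycle genes 24 fell and 3 rose (median -0.64, adjusted p = 2.0e-19), and Mki67 went from 297 to 177 CPM. The sterol synthesis list (12 rises of 20, 1 fall adjusted over the list alone, adjusted p = 0.0419; adjusted p = 0.322 with an estimated correlation) and the iron handling list (6 rises and 2 falls of 11, 7 rises adjusted over the list alone, adjusted p = 0.0323; adjusted p = 0.0905 with an estimated correlation) lost their calls with total counts only (adjusted p = 0.115 and 0.0660) and with the stricter count filter (0.0721 and 0.0611). The sterol call was also lost without day 7 replicates 1 or 4 or day 14 replicates 3 or 4 (adjusted p 0.0548 to 0.0647). Over all alternatives these p-values ran from 7.6e-05 to 0.322 and from 0.0121 to 0.0905. The call of the stress list (13 rises and 3 falls of 18, adjusted p = 0.0281; adjusted p = 0.149 with an estimated correlation) was lost with total counts only too (adjusted p = 0.0843, range over the alternatives 2.5e-05 to 0.149). BMP and TGF-beta genes gave 14 rises and 4 falls of 25 (15 and 5 adjusted over the list alone; adjusted p = 0.0028; adjusted p = 0.0739 with an estimated correlation), with Gdf5, a joint and cartilage growth factor, rising by 1.51.

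**Figure D4:**
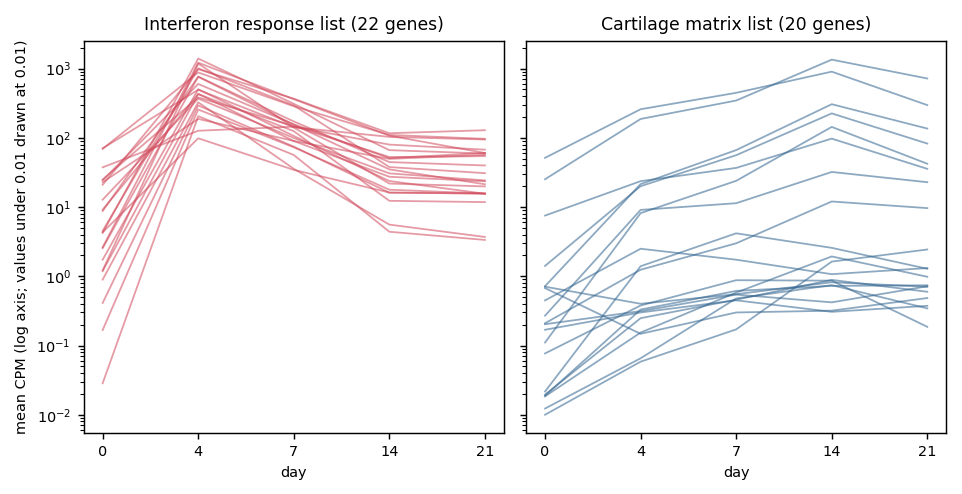
Lines give the mean level, in CPM on a log axis, of the 22 interferon response genes and the 20 cartilage matrix genes on each sampling day, with values under 0.01 drawn at 0.01. Of the interferon genes 21 are highest on day 4, and of the 18 cartilage matrix genes that changed over time 12 are highest on day 14.

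Between day 14 and day 21 most matrix lists fell. Col2a1 went from 1349.8 ± 99.7 to 721 ± 69.9 CPM (-0.91 ± 0.06) and Acan from 226 ± 17.3 to 82.8 ± 9.67 CPM (-1.45 ± 0.07). No cartilage matrix gene rose and 12 of 20 fell (median -0.75, adjusted p = 4.5e-07), among them Hapln1 (-1.77 ± 0.09) and Col11a1, a chain of the cartilage collagen fibril (-1.61 ± 0.05, 905 to 297 CPM). Of 39 collagen chains 28 fell and 2 rose (29 falls adjusted over the list alone; median -0.91, adjusted p = 2.2e-30), and of 28 collagen processing genes 27 fell (median -0.54, adjusted p = 5.2e-20). Col1a1 (-0.98 ± 0.04), Col1a2 (-0.81 ± 0.03) and Col3a1 (-1.12 ± 0.04) were all lower on day 21. The fibroblast and tendon list gave 16 falls and 1 rise of 20 (17 falls adjusted over the list alone; median -0.90, adjusted p = 2.5e-31), with the tenascin gene Tnc going from 656 to 203 CPM. In the osteoblast and mineralisation list 14 of 16 fell (1 rise adjusted over the list alone; median -0.99, adjusted p = 1.1e-21), for example the sphingomyelinase gene Smpd3 (-2.02) and the mineral regulator Dmp1 (-1.86). The proteoglycan list gave 11 falls and 1 rise of 15 (median -0.76, adjusted p = 9.3e-18), and basement membrane genes 12 falls and 4 rises of 19 (median -0.59, adjusted p = 2.1e-06).

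Hypertrophic chondrocyte genes split in this step. Of 18 members 12 fell and 4 rose (median -0.48, adjusted p = 2.7e-09). Col10a1 rose by 0.76 ± 0.11 to 23.8 ± 3.33 CPM (adjusted p = 3.8e-07), and Spp1 went from 1928 to 2435 CPM. Ibsp, by contrast, went from 1736 ± 117 to 359.97 ± 36.3 CPM (-2.27 ± 0.07) and Alpl from 463 ± 5.78 to 171 ± 14.6 CPM (-1.43 ± 0.04). Runx2 changed by -0.57 ± 0.04, Ihh by -1.60 ± 0.46 and Panx3 by -1.66. Mmp13 was at 2.92 and 2.63 CPM (adjusted p = 0.616). Of 17 chondrogenic regulators 9 fell and 1 rose (median -0.28, adjusted p = 0.00050), and Sox9 changed by -0.28 ± 0.04 to 163 ± 10.5 CPM. Col9a1 (-0.50 ± 0.13, adjusted p = 0.0012) was not called by DESeq2 (adjusted p = 0.0693, range over the alternatives 1.7e-09 to 0.0693). Comp (-0.32 ± 0.13, adjusted p = 0.0372) lost its call with total counts only, with the stricter count filter and without each of 6 single libraries in turn, all 4 of day 14 and replicates 1 and 4 of day 21 (adjusted p 0.0569 to 0.252 in those fits, 0.0055 to 0.252 over all alternatives).

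Sterol synthesis genes fell together, 19 of 20 with none rising (median -0.54, adjusted p = 6.8e-17). Hmgcs1, an early enzyme of the pathway, went from 446 to 274 CPM, and Msmo1 (-0.90) and Fdps (-0.84) fell as well. Of 22 Wnt genes 15 fell and 2 rose (median -0.51, adjusted p = 2.3e-05), with the secreted inhibitor Wif1 going from 90.3 to 27.0 CPM. Of 20 matrix proteases and inhibitors 12 fell and 2 rose (median -0.32, adjusted p = 1.8e-06), and of 13 insulin-like growth factor genes 8 fell and 4 rose (median -0.39, adjusted p = 0.00016), Igfbp5 from 12937 to 5307 CPM. The other largest falls were in Kctd12 (-2.65 ± 0.11), the collagen chain Col6a6 (-2.35 ± 0.11), the adipokine-like C1qtnf3 (-2.23 ± 0.07), the basement membrane protein gene Hmcn1 (-2.20 ± 0.10) and Shisa2 (-2.16 ± 0.17). The largest rises were smaller. Pim1, a survival kinase, went from 20.9 to 74.8 ± 8.76 CPM (1.84 ± 0.07), and Cd68, a lysosomal protein gene abundant in macrophages, from 11.6 to 31.0 ± 1.99 CPM (1.41 ± 0.10). N4bp2l1 (1.44 ± 0.09), the signalling adaptor Gab2 (1.41 ± 0.10), the orphan receptor gene Gprc5a (1.37 ± 0.10) and Dennd11 (1.34 ± 0.11) were the others.

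Several list calls of this step were lost with an estimated correlation. They were smooth muscle and myofibroblast (8 falls and 1 rise of 11; adjusted p = 0.0029, and adjusted p = 0.0503 with an estimated correlation), mitochondrially encoded mRNAs (7 falls of 8, 8 adjusted over the list alone; adjusted p = 0.00021, and adjusted p = 0.186 with an estimated correlation), BMP and TGF-beta (14 falls and 5 rises of 25; adjusted p = 0.0038, and adjusted p = 0.0954 with an estimated correlation) and hedgehog response (4 falls and 2 rises of 10; adjusted p = 0.0282, and adjusted p = 0.111 with an estimated correlation). Adipocyte genes gave 4 rises of 7 (adjusted p = 0.0360; adjusted p = 0.0764 with an estimated correlation, 0.0565 with total counts only and 0.0360 to 0.0764 over the alternatives). Cell cycle genes gave 18 falls and 6 rises of 30 (median -0.16, adjusted p = 0.0212; adjusted p = 0.358 with an estimated correlation, 0.257 with total counts only and 0.00018 to 0.358 over the alternatives). The interferon list was not called (12 falls and 2 rises of 22, adjusted p = 0.0888), except without a count filter or without day 14 replicates 2 or 4 or day 21 replicate 2 (adjusted p 0.0058 to 0.0389, and 0.0058 to 0.636 over all alternatives). Nor were the glycolysis and hypoxia genes called (10 falls and 5 rises of 22, adjusted p = 0.324).

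Set against day 0, many matrix genes were still higher on day 21. Col2a1 was 28.6-fold higher (4.84 ± 0.08, adjusted p = 3.6e-35), and Acan (5.87 ± 0.12), Col9a1 (6.38 ± 0.25), Comp (5.62 ± 0.24) and Col10a1 (7.13 ± 0.22) were higher too. Of 20 cartilage matrix genes 17 rose and none fell (median 4.80, adjusted p = 3.1e-11), and of 18 hypertrophic chondrocyte genes 14 rose and 3 fell (median 2.68, adjusted p = 6.5e-14). Matrix and bone lists whose calls were lost with an estimated correlation were fibroblast and tendon (17 rises and 3 falls of 20; adjusted p = 3.3e-07, and adjusted p = 0.0622 with an estimated correlation), basement membrane (15 rises and 3 falls of 19; adjusted p = 1.4e-05, and adjusted p = 0.0687 with an estimated correlation), collagen processing (17 rises and 7 falls of 28, 19 rises adjusted over the list alone; adjusted p = 0.00092, and adjusted p = 0.290 with an estimated correlation) and osteoblast and mineralisation (10 rises and 4 falls of 16; adjusted p = 0.0227, and adjusted p = 0.149 with an estimated correlation). Snorc, a cartilage transmembrane proteoglycan gene, was at least 93.6-fold higher, with no counts on day 0. Sox9 rose by 0.47 ± 0.04, Col1a1 by 0.45 ± 0.04 and Col3a1 by 1.31 ± 0.04. Runx2 (-0.31 ± 0.04), Alpl (-0.23 ± 0.04) and Col1a2 (-0.63 ± 0.03) were lower on day 21 than on day 0. Prg4, the lubricin gene, was at 0.708 and 0.705 CPM and was not called in any of the 7 comparisons (day 4 against day 0 was called without day 0 replicate 3, adjusted p = 0.0489, range over the alternatives 0.0489 to 0.504). Matn3 was at 0.0769 and 0.186 CPM (adjusted p = 0.0909), and was called by limma-voom (adjusted p = 0.0158) and without day 0 replicate 3 (adjusted p = 0.0011, range over the alternatives 0.0011 to 0.254).

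The largest rises over the whole course were in Apod (0 to 22.3 CPM), Oas1g (0 to 6.57 CPM), the vasodilator peptide gene Adm (9.34 ± 0.23, 0.0447 to 30.8 CPM), Gbp8 (9.05 ± 0.20), F13a1 (9.02 ± 0.10, 0.369 to 201 CPM) and Ifi44l (0 to 2.08 CPM). All 22 interferon genes were still above their day 0 level (median 2.28, adjusted p = 2.8e-17). All 22 glycolysis and hypoxia genes were higher (median 1.57, adjusted p = 1.2e-33), Egln3 going from 1.10 to 117 CPM, as were all 7 adipocyte genes (median 2.67, adjusted p = 0.00020). Wnt genes gave 16 rises and 3 falls of 22 (median 1.17, adjusted p = 0.00041), insulin-like growth factor genes 9 rises and 3 falls of 13 (median 0.95, adjusted p = 1.2e-05), the proteoglycan list 12 rises and 1 fall of 15 (median 2.72, adjusted p = 1.2e-22) and collagen chains 28 rises and 5 falls of 39 (median 1.47, adjusted p = 5.9e-07). In the unfolded protein and amino acid stress list 13 of 18 rose and 2 fell (median 0.52, adjusted p = 9.6e-06). Of 30 cell cycle genes 29 fell and 1 rose (median -1.25, adjusted p = 1.9e-21). Hedgehog response genes fell, 9 of 10 with 1 rise (median -0.87, adjusted p = 0.00070), among them the receptor genes Ptch1 (-1.31) and Gas1 (-2.34, 1391 to 274 CPM). The largest falls were in Asb4 (-3.62 ± 0.14), Eif1ad10, a member of a multi-copy family (-3.49 ± 0.12), Plxna4 (-3.43 ± 0.11), the kinase gene Ttbk1 (-3.36 ± 0.16), the imprinted gene Peg10 (-3.15 ± 0.04, 1823.1 to 205 CPM) and Kif26b (-3.08 ± 0.10). Sterol synthesis genes gave 17 falls and 2 rises of 20 (adjusted p = 0.00044; adjusted p = 0.111 with an estimated correlation).

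Other lists gave no call by camera, which compares a list with all other genes, on day 4 against day 0. Fry, which makes no such comparison, called all of them except glycosaminoglycan synthesis (fry adjusted p = 0.171) and skeletal muscle (0.116). Fry gave, for example, 8.7e-12 for cell cycle exit, upward, and 1.6e-08 for hedgehog response, downward. The p-values below are those of camera. Selenoproteins, of interest because selenite was added, gave 8 rises and 11 falls of 20 there (adjusted p = 0.473). Iron handling genes gave 5 rises and 4 falls of 11 there (6 rises adjusted over the list alone; adjusted p = 0.917), while the transferrin receptor gene Tfrc fell from 306 to 95.2 CPM. Cell cycle exit genes gave 8 rises and 4 falls of 13 (adjusted p = 0.0594; called after leaving out each day 4 library in turn, range over the alternatives 0.0370 to 0.149). Glycosaminoglycan synthesis gave 9 rises and 10 falls of 27 (10 rises adjusted over the list alone; adjusted p = 0.687), chondrogenic regulators 7 and 7 of 17 (adjusted p = 0.726), BMP and TGF-beta 13 and 9 of 25 (adjusted p = 0.719), sterol synthesis 6 and 11 of 20 (adjusted p = 0.216) and hedgehog response 2 and 5 of 10 (adjusted p = 0.129). Lists of other tissues held few measured genes. On day 4 against day 0 skeletal muscle gave 1 rise of 3 (none adjusted over the list alone; adjusted p = 0.922), smooth muscle 9 rises and 2 falls of 11 (adjusted p = 0.411; 0.0107 without a count filter, range over the alternatives 0.0107 to 0.539), adipocyte 4 rises and 1 fall of 7 (adjusted p = 0.361), endothelial 4 rises of 5 (adjusted p = 0.516), neural and glial 3 rises and 2 falls of 9 (adjusted p = 0.726), and epithelial and pluripotent 3 rises of 4 (adjusted p = 0.726). Leukocyte and osteoclast markers gave 3 rises of 6 (adjusted p = 0.317), with Mpeg1, a macrophage pore protein gene, going from 0.0310 to 7.60 CPM. Of the 160 list tests 95 were called by camera with the preset correlation and 55 of these hold with an estimated correlation. These are the interferon call for day 4 against day 0 and every list call given above without a second adjusted p. Some hold narrowly. On day 4 against day 0 the estimated correlation gave adjusted p = 0.047 for basement membrane and 0.0455 for Wnt genes. On day 7 against day 4 it gave 0.047 for basement membrane and for collagen chains.

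**Figure D5:**
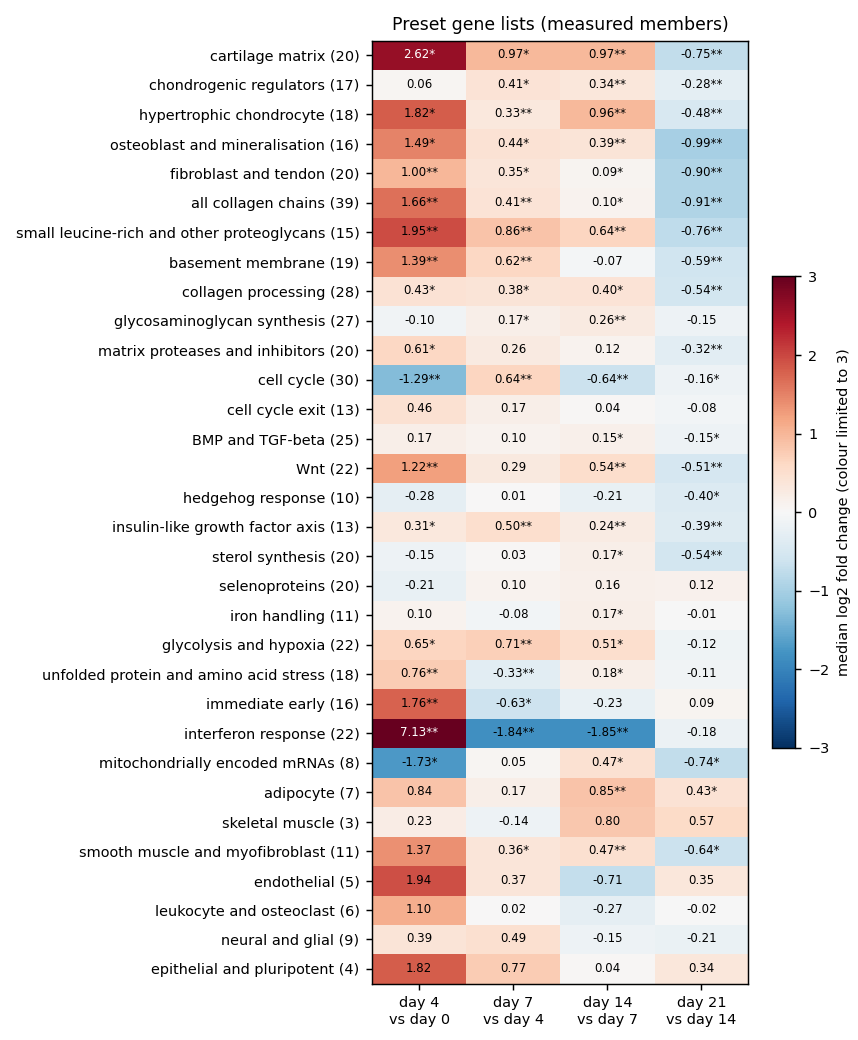
Colours give the median log2 fold change of the measured members (number in parentheses) of 32 gene lists in the 4 comparisons of consecutive days, limited to 3 in either direction, with 2 stars for calls that hold with an estimated correlation and 1 star for calls made only with the preset one. The interferon list reaches 7.13 on day 4 and -1.85 on day 14, and the collagen chains -0.91 on day 21.

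Over the whole course 15100 genes differed between days, and 7263 of them spanned at least 2-fold between their lowest and highest day mean. Of these 15100 genes 4546 were highest on day 0, 3647 on day 4, 1294 on day 7, 2085 on day 14 and 3528 on day 21. The clearest genes with a day 0 maximum were Peg10 (1823.1 CPM on day 0 and 205 on day 21, adjusted p = 6.0e-40), the chemokine gene Cxcl12 (1991.5 to 563.5 CPM), Lgr4 and the splicing factor gene Sfpq (452 to 112 CPM). Day 4 maxima were led by Mx1 (adjusted p = 3.9e-45), Zbp1, Parp14 (16.9 CPM on day 0, 722 on day 4) and Oas2. Npnt, an integrin ligand of basement membranes, was highest on day 7 at 90.2 CPM (2.46 on day 0, 34.2 on day 21, adjusted p = 3.9e-38), as were the ion channel genes Cacna1g (214 CPM) and Piezo2 (104 CPM) and the matrix protein gene Dpt (76.3 CPM). Prss35 (adjusted p = 9.4e-45), Igfbp4 (529 CPM), F13a1 and Dcn (192 CPM) were highest on day 14. Spp1 (2435 CPM, adjusted p = 8.2e-39), the ectonucleotidase gene Nt5e (119.6 CPM), the protease gene Htra1 (253 CPM) and Ndrg1 (395 CPM) were highest on day 21.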

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

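Among the tests below, those for mixed-in leukocytes, for reads shared between related genes, for receptor genes without Or2v1, for reads spread evenly over genes and for the scaling of the cartilage list were chosen only after the result was seen.

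The interferon response list was higher on day 4 than on day 0, from 326 to 12923 summed CPM. Leukocytes mixed into the day 4 cultures would bring their own abundant transcripts, but the rise of 8 leukocyte markers was only 0.0689% of that of the list (0.574 to 9.25 CPM). Most of it was Mpeg1, which reached 7.60 CPM, while Ptprc was at 0.0467 and 0.0442 CPM and Tyrobp and C1qa had no counts on either day. Reads shared between related genes do not account for it either, since all 13 members outside the Ifit, Oas and Ifi families rose, with a median log2 change of 5.56 (range 3.04 to 10.00). A response of the cultures may explain the pattern, but day 4 differs from day 0 in medium and age together, and what would start such a response was not tested.

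From day 0 to day 4 more genes rose than fell at least 2-fold (2880 and 1235). Counts of 2005 olfactory and vomeronasal receptor genes, which read genomic DNA or other background, were 7.67 times higher on day 4 (15.9 ± 1.83 to 122 ± 8.04 CPM), and still 2.67 times higher (15.1 ± 1.70 to 40.4 ± 2.67 CPM) without Or2v1, which made up 76.2% of the rise. This is what background reads in the day 4 libraries would give, but reads spread evenly over genes do not account for it. Of the other 2004 receptor genes 89.2% had no count in the day 4 libraries. If their 3819 counts were spread evenly, 14.9% would have none, with an SD of 0.795 points for that expected share. Depth was tested by thinning all libraries to 21523358 counts, which left 70.4% of the 2-fold genes rising (2670 and 1122 genes) against 69.988% before, and among genes with a mean of at least 10 CPM 883 rose and 314 fell at least 2-fold. Unevenly placed background reads therefore remain open as a source of part of the rises, as does the difference in medium and time, which the design names and which may explain them but was not tested apart.

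The cartilage matrix list was lower on day 21 than on day 14 (median log2 change -0.75, quartiles -1.24 and 0.06). Length and GC content of the transcripts are excluded as the whole cause: their trend ran from -0.49 to 0.09 over genes of known transcript length, and taking it out left 439 of 7448 changed genes within 2 SE of 0 where none was before. Over the list it ran from -0.11 to 0.05, so the median after it was -0.76 (quartiles -1.24 and 0.03) and 12 of the 12 members that fell kept a fall beyond 2 SE. With total counts only the median was -0.61 (adjusted p = 5.0e-09), so the fall held with TMM scaling and with total counts. Total counts are themselves swayed by abundant genes, so this test cannot exclude scaling set by a few of them. A decline of cartilage matrix expression in the oldest cultures may be a biological difference between the days. This remains a hypothesis because it was found and tested on the same libraries.

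Counts of changed genes were compared among 35 splits of the libraries (60 for the test over time). In each test only the real assignment to days gave as many genes. Libraries of a day lay closer to one another than to those of other days, which by itself puts the real assignment first. Since the replicates may be technical, the splits cannot tell an effect of the day from a difference between single cultures. The real count and the highest other split were 11382 and 8537 for day 4 against day 0, 8664 and 5493 for day 7 against day 4, 7793 and 1 for day 14 against day 7, and 7766 and 2 for day 21 against day 14. Against day 0 they were 11721 and 0 for day 7, 11895 and 1 for day 14 and 12530 and 0 for day 21, and over time 15100 and 1736. In the comparisons of 3 libraries with 4, the 4 other splits with over 100 genes point to a structure of the libraries. The highest of these for day 4 put 3 day 0 libraries against the remaining 1 and all of day 4, and that for day 7 put 1 day 7 library with all of day 4, so each nearly mirrors the real assignment.

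A single library lay apart from the other 3 of its day in 22 of 345 tested sets of 4 libraries. That is near the share of about 1 in 20 that chance gives, so single cases below may be chance. Day 4 with 3 libraries was not tested. Each ratio below is the gap to the nearest other library divided by the range of all 4. On day 0, Matn3 was high in replicate 3 (ratio 0.913, 0.283 CPM against at most 0.0246) and Ihh in replicate 2 (ratio 1, 0.0433 CPM from 1 count, against 0). Replicate 4 was high in Col1a1 (ratio 0.881, 3850.3 CPM against at most 3435.5) and Zbp1 (ratio 0.916, 0.226 against at most 0.0865). Replicate 2 was high in Selp (ratio 0.874, 69.8 against at most 68.2) and low in Kctd12 (ratio 0.856, 8.83 against at least 10.4) and Kif26b (ratio 0.911, 27.1 against at least 31.2). Col6a6 was high in replicate 3 (ratio 0.898, 1.01 against at most 0.492) and Peg10 in replicate 1 (ratio 0.906, 1980.1 against at most 1783).

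On day 7, replicate 4 was low in Mmp13 (ratio 0.846, 0.203 CPM against at least 0.398) and high in Cxcl10 (ratio 0.840, 39.7 against at most 34.8). Oas3 was high in replicate 3 (ratio 0.830, 237 against at most 215) and Igfbp4 low in replicate 1 (ratio 0.884, 278 against at least 288). On day 14, replicate 1 was high in the share of Rn18s-rs5 (ratio 0.847, 1.81% against at most 1.47%) and in Col9a1 (ratio 0.958, 35.3 CPM against at most 31.2). Replicate 3 of day 14 was high in Cxcl10 (ratio 0.850, 7.61 against at most 5.18) and Pim1 (ratio 0.8845, 24.9 against at most 19.8). On day 21, the total of replicate 4 was 45390936 counts against at most 24018868 (ratio 0.895), and it was high in Nt5e (ratio 0.870, 127 CPM against at most 118). Replicate 1 was low in Susd5 (ratio 0.862, 56.6 against at least 58.3). Replicate 2 was high in Rsad2 (ratio 0.883, 22.7 against at most 19.2) and Mx2 (ratio 0.833, 18.2 against at most 13.3).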

How the results depend on the processing

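The fit without ribosomal RNA and mitochondrial genes, and the lists without a low-count filter, were chosen only after the data were seen. No result turned its direction while called under any alternative. Of the counts of changed genes, 1 total moved by over 1.5 times. Genes changed at least 2-fold between days 14 and 21 numbered 590 (243 rose, 347 fell) with at least 1 CPM in at least 3 libraries, against 922, because that filter tests fewer genes (13897 against 16483). With it the 2-fold falls against day 0 were 743 and not 1235 on day 4, 486 and not 873 on day 7, and 822 and not 1295 on day 14. With total counts only, 5872 genes rose and 2595 fell between days 14 and 21, against 3423 and 4343. Whether more genes rose or fell from day 4 to day 7 (4385 and 4279) turned with DESeq2 (4212 and 4495), limma-voom (4385 and 4410), RLE scaling (4180 and 4506), the stricter filter (4147 and 4234), both days alone (4453 and 4509) and without day 4 replicates 1, 2 or 4 (3947 and 4204, 3925 and 4153, 3828 and 3838). With total counts only, 839 rose and 743 fell at least 2-fold in that step. From day 7 to day 14 (3909 and 3884) it turned with no filter (3701 and 3710), without ribosomal RNA and mitochondrial genes (3872 and 3917) and without day 14 replicates 1 or 3 (3639 and 3653, 3660 and 3664). From day 14 to day 21 it turned with the stricter filter (3836 and 3773), and for 2-fold genes with no filter (527 and 518). Leaving out 1 library at a time gave 10707 to 11160 changed genes for day 4 against day 0 (2-fold 3913 to 4210), 7666 to 8329 for day 7 against day 4 (1390 to 1542), 7176 to 7390 for day 14 against day 7 (1078 to 1158) and 7058 to 7424 for day 21 against day 14 (783 to 927). Against day 0 it gave 11251 to 11424 for day 7, 11470 to 11648 for day 14 and 12045 to 12289 for day 21, and 14806 to 15353 over time. Those fits kept 85.8% to 96.8% of the called genes, and none was called in the opposite direction. With a block for the replicate number the counts were 11300 for day 4 against day 0, 8569, 7743 and 7711 for the later steps, 11695, 11858 and 12501 for days 7, 14 and 21 against day 0, and 15023 over time. The block changed no call of a named gene or list. No pairing of libraries by number was seen. Same-numbered deviations correlated at -0.07 to 0.07 over 36 pairs, and 4 of 19 libraries correlated best with their own number. All tested genes count alike in these correlations, so noise of scarce genes could hide a weak pairing.

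Of 172 gene results, all kept their call with RLE scaling, with the block and without ribosomal RNA and mitochondrial genes. DESeq2 kept 170 (1 gained, 1 lost), limma-voom 168 (2 gained, 2 lost), total counts only 169 (3 lost) and no filter 170 (1 gained, 1 lost). Not all 172 could be tested with the stricter filter, which kept 150 and lost 1, or in fits of both days alone, which kept 164 and gained 1. Leaving out single libraries gave several fits per result, of which 1302 kept the call, 5 gained and 13 lost it. Of 160 list results, the block and RLE scaling kept all, total counts only 153 (2 gained, 5 lost), the stricter filter 155 (5 lost), no filter 148 (11 gained, 1 lost), and an estimated correlation 120 (40 lost). Without ribosomal RNA and mitochondrial genes 154 kept theirs and 1 was gained, and the mitochondrial list had no value. Of the fits without single libraries, 1194 kept a list call, 17 gained and 5 lost it. Depth limits what can be said of genes near 0.0631 to 0.134 CPM, the level of 3 counts in a library. Ihh on days 0, 4 and 7 and Col10a1 and Matn3 on day 0 lie near or under it.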

Other observations

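The gene groups below were chosen after the data were seen, so all their tests were chosen only after the result was seen. Antigen presentation genes moved with the interferon response. All 11 measured genes of MHC class I presentation rose from day 0 to day 4 (median log2 change 2.77, adjusted p = 2.2e-40 over 25 tests, and 2.7e-06 with an estimated correlation). H2-K1 went from 109 ± 5.22 to 1865.8 ± 120.4 CPM, H2-D1 from 171 ± 15.3 to 1986 ± 118 CPM, and B2m, the light chain of class I molecules, from 268 ± 12.5 to 1831 ± 99.1 CPM. All 11 fell from day 4 to day 7 (median -1.04) and from day 7 to day 14 (median -0.80), and on day 21 against day 0 there were 9 rises and 2 falls. H2 genes share similar sequence, so the division of reads between them is uncertain. Ifnb1, which encodes interferon beta, was at 0.0680 ± 0.0794 CPM on day 0, 2.17 ± 0.469 on day 4 (195 counts) and 0.150 ± 0.0642 on day 7. Ifna4 had counts on day 4 only (27 counts, 0.248 ± 0.174 CPM), too few to set apart from the background reads left open above for those libraries. The double-stranded RNA receptor gene Tlr3 went from 10.3 to 469.9 CPM between days 0 and 4, the transcription factor gene Irf1 from 29.0 to 214 CPM and the RNA-editing enzyme gene Adar from 36.2 to 279.7 CPM. On the same days Irf3 was at 20.5 and 21.7 CPM and the receptor gene Ifnar1 at 90.4 and 75.8 CPM.

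Ribosome, mitochondria and lysosome genes changed as groups with the preset correlation. Of 80 cytosolic ribosomal protein genes 79 fell from day 0 to day 4 (median -0.76, adjusted p = 1.2e-20; adjusted p = 0.156 with an estimated correlation). From day 4 to day 7 and again from day 7 to day 14, 73 rose (medians 0.26 and 0.45; adjusted p = 0.353 and 0.0722 with an estimated correlation). Nuclear respiratory chain genes gave 55 falls of 79 on day 4 (median -0.30; adjusted p = 0.398 with an estimated correlation) and 57 rises on day 14 against day 7 (median 0.28; adjusted p = 0.236 with an estimated correlation). Of 53 lysosomal genes 47 rose and 3 fell between day 0 and day 21 (median 0.79, adjusted p = 1.2e-15; 0.0303 with an estimated correlation). The membrane protein gene Lamp1 went from 580.2 ± 15.7 to 1005 ± 29.8 CPM, and the cathepsin genes Ctsb from 193 to 425 CPM and Ctsd from 79.1 to 180.0 CPM. Nos2, which makes nitric oxide, rose through the series from 0.163 CPM on day 0 to 17.6, 23.2, 35.4 and 65.8 CPM on days 4, 7, 14 and 21. Genes of the p53 response gave 8 rises and 4 falls of 15 on day 4 (adjusted p = 0.144) and 11 rises and 4 falls on day 21 against day 0 (median 0.27, adjusted p = 0.0064; 0.0448 with an estimated correlation). Among them Gadd45a went from 6.44 to 50.4 CPM between days 0 and 4. Apod stood at 370.4, 141, 40.0 and 22.3 CPM on days 4, 7, 14 and 21 after 0 counts on day 0.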
